A study of Mus musculus with 18 samples.

How the data were processed

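RNA of 18 samples from gonadal adipose, hypothalamus and liver was sequenced after poly-A selection, per the labels' protocols. Reads were processed with HISAT 0.1.6, a spliced aligner, and StringTie 1.0.4, a transcript assembler, on the mouse build mm10, per the submitters' processing notes. The name of the deposited workbook carries the word Cufflinks, another assembler. Its part in these assemblies, the tool that merged them, the annotation and the strandedness of the libraries are not stated in the sources used here. The deposited tables comprise 6 files, a gene table and a transcript table per tissue. Per the file headers, a transcript table gives the chromosome, strand, start, end, identifier and gene name of each model of 1 merged assembly per tissue, and 6 FPKM columns.

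The 36 FPKM columns in the 6 tables were not used. Their headings give a tissue and a number, and none of the 8 distinct numbers occurs in the labels, so no column could be assigned to a sample or a treatment. Although the headings would allow a comparison of expression between tissues, columns without a sample or group enter no result here. There were 4 numbers present in all 3 tissues, and hypothalamus and liver shared all 6 of theirs. The planned comparison of BPA with vehicle, by limma on log2 FPKM, with its gene set tests and its overlap between tissues, was not run for that reason. An early attempt to sum and correlate the FPKM columns stopped on cells that spreadsheet software had turned into dates or times, before it gave any value. After that the columns were only searched for such cells. The depth per sample is unknown, and no value here has an error between replicates.

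Everything reported was computed from the positions and names of the transcript models. Starts and ends in base pairs are as deposited. Between 11171 and 11173 distinct model spans per tissue equalled a gene of the RefSeq table of the same build exactly, against 11 to 22 after adding 1 to the start, so positions were taken as counted from 1. The number of models was counted per gene name and tissue. A gene was said to have the most models in a tissue when it had at least 1 more there than in both other tissues. This number depends on depth, on the length of a gene, on overlapping neighbours and on paralogs as well as on the RNA present, and it is not an expression level. Genes that overlap or have near-identical copies can exchange models, and their numbers are uncertain.

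The gene lists and a set of genes of interest were fixed before the data were examined, for the planned comparison of treatments. The model number as a measure was chosen after the tables were seen. The sums of additional models per list and the leading genes had also been looked at before the ranking statistic, its background and its matching were settled. Of 40 lists, 39 had at least 5 members in the tables. The list of mitochondrially encoded transcripts had fewer than 5 under those names and was not ranked. For each list and tissue, the number of members with the most models was ranked among 10000 random lists of the same size. Random members were protein-coding genes of GENCODE release M21 (19540 genes), matched on the fewest models in any tissue (5 groups) and on gene span (5 groups). Ties with the observed number were divided evenly between lower and higher. In the largest matching groups genes were drawn with replacement. A few list members are not protein-coding, among them 5 of the 29 imprinted genes in the tables. The lists hold 945 genes in all, 39 of them in more than 1 list, so the 117 percentiles are not independent. A percentile describes these 3 assemblies and is not a p-value. On simulated data with all 23905 genes, a gain of models in liver was given to 200 genes. The list of those genes ranked at percentile 100, and 4.33% of the percentiles of lists without a gain were at or above 95. The lists without a gain were drawn at random from the background genes, so a low share was fixed by the design. Apart from the gain given, simulated gains had the same mean in every tissue and were independent between genes, and spans were random. The data need not follow these settings.

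The planned rule for naming genes needs a test and could not be applied to leading genes. They were taken from the 20 genes per tissue with the largest lead in models over the higher of the other tissues. Left out were Gm, LOC, Mir, Snor, ENSMUSG and Rik names and names starting with a digit or with a capital letter and a digit. This filter also removed some proper symbols, such as C3, and kept the clone name BC024386 in liver. The few genes described were picked from the 20 after their values were seen. The planned rule names 2 to 4 members per list by their p-value; examples here were instead picked among members with the most models in the tissue, also after their values were seen. The genes of interest fixed beforehand are given whatever their values, except 1 that is not reported here.

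Loci in which every model lacks a gene name were compared with GENCODE exons and genes, and between tissues, by an overlap of at least 1 bp regardless of strand unless stated. Shares have 95% Wilson intervals. For a test in the closing observations, each locus was placed 20 times at random over the chromosomes. The odds ratio given there is a Mantel-Haenszel estimate over groups of genes of similar span. Alternatives were counting models of 1 span once, requiring a lead of at least 2 models, using protein-coding genes alone, leaving gene span out of the matching, keeping only loci with a strand, those of at least 500 bp or those on the main chromosomes, and requiring a reciprocal overlap of at least 50%. All were chosen after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.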

Results

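RNA was sequenced from the gonadal adipose tissue, hypothalamus and liver of male C57BL/6 mice aged 3 weeks. Their dams had received bisphenol A (BPA), an estrogenic plastics chemical, by daily gavage at 5 mg/kg from day 1 to day 20 after conception, or corn oil alone. The labels list 18 samples, with 3 BPA and 3 vehicle samples in each of the 3 tissues. The study was designed to ask what prenatal BPA does to the transcriptome of each tissue. That comparison was not made here, because the numbers heading the expression columns occur in none of the sample labels and no column could be placed in a treatment group. The headings do name the tissue, but expression columns without a sample or treatment group were not used in any comparison. What was compared instead was the set of transcript models assembled for each tissue, of which there is 1 per tissue. These assemblies are not divided by treatment, so each may hold models from BPA-exposed as well as vehicle mice. A transcript model is a stretch of the genome, with a strand where one was assigned, that is listed as a separate transcript of the assembly. A listed model is not by itself evidence that its RNA was present, since nearly all gene names occurred in all 3 assemblies. The sequencing depth behind each assembly is unknown, and there are no replicate assemblies. Differences in model number between tissues are therefore given with no test and no replicate error.

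The hypothalamus assembly held 65611 transcript models, the adipose assembly 60420 and the liver assembly 51785. Of 23905 gene names, 23904 occurred in all 3 assemblies, so the presence of a name says nothing about whether the gene was active. The number of models under a name did differ. It was the same in all 3 tissues for 12195 genes and differed for 11710. The hypothalamus had the most models, by at least 1 over both other tissues, for 4954 genes, adipose for 2908 and liver for 1870, and 1978 genes were tied for the most. The mean was 2.52 models per gene name in hypothalamus, 2.22 in adipose and 2.03 in liver. Gene positions below are on mm10 and run from the lowest start to the highest end of a gene's models over all tissues.

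Among the 20 genes with the largest lead in adipose was Plin4. Plin4, a lipid droplet coat protein (chromosome 17, 56100531 to 56117590), had 84 models in adipose, 8 in hypothalamus and 4 in liver. Adrb3, the adrenergic receptor that drives lipolysis (chromosome 8, 27222436 to 27250867), had 16, 2 and 3 in the same order. Car3, a carbonic anhydrase abundant in fat (chromosome 3, 14755552 to 14872663), had 12, 1 and 3. Among genes whose names passed the filter on symbols, the largest lead in adipose was that of Ahnak, a giant scaffold protein (chromosome 19, 8989194 to 9077006). It had 195 models in adipose against 4 and 7. Ahnak and Plin4 both encode long internal repeats. Tnxb, an extracellular matrix protein, had 42, 3 and 7 models, and Ttn, the giant protein of the muscle sarcomere, had 20, 2 and 2. Ankef1, with 26, 4 and 1 models, and Tspan12, with 24, 3 and 4, ranked directly after Tnxb. The 20 leading genes of a tissue were not tested for a shared function, here or in the other tissues.

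Gene lists fixed beforehand were ranked against random lists of genes with a similar fewest number of models and a similar span. Of 25 adipocyte markers, 12 had the most models in adipose, against a median of 4 in random lists, at the 100th percentile of 10000 random lists. Beside Plin4, Adrb3 and Car3 they included Cidec, a lipid droplet fusion protein, with 9 models in adipose, 1 in hypothalamus and 5 in liver, and Adipoq, which encodes adiponectin, with 2, 1 and 1. Of 32 markers of the epididymis and male gonad, 13 had the most models in adipose, also at the 100th percentile, and 0 had the most in hypothalamus. Spink8 and Wfdc10, both protease inhibitors of the epididymis, had 5 models in adipose and 1 in each other tissue. Sycp3, a component of the meiotic chromosome axis, had 14, 5 and 3, and Lcn5, an epididymal lipocalin, had 6, 3 and 3. Among other gonad members, Dazl and Ddx4 had 2 models in every tissue, and Prm1, Tnp1, Insl3 and Star had 1. The epididymal members Crisp1, Gpx5, Adam7, Cst8 and Cst11 also had 1 model in every tissue. Mesothelial markers, which label the lining of the body cavity, had 6 of 16 members with the most models in adipose (percentile 99.6), among them Wt1 with 5, 1 and 2 models and Upk3b with 3, 1 and 1.

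Lists for blood vessels, connective tissue and muscle ranked high as well. Endothelial markers had 7 of 18 members with the most models in adipose (percentile 99.4), including Sox17, a transcription factor of arteries, with 13, 6 and 6 models. Genes of the fibrillar collagens and extracellular matrix had 8 of 25 (percentile 97.7), including Col1a2 with 8, 2 and 2 models and Col3a1 with 3, 1 and 1. Muscle markers had 7 of 24 (percentile 98.0), including Myl1, a skeletal muscle light chain, with 7, 2 and 2 models, and Myh11, a smooth muscle myosin, with 10, 4 and 2. Other muscle markers had the most models in hypothalamus (6, percentile 62.5) or liver (3, percentile 73.1). Those of hypothalamus included Mylpf with 2, 5 and 2 models and Atp2a1 with 1, 3 and 1. Immediate early genes, which respond within minutes to stimulation and to tissue handling, had 8 of 25 with the most models in adipose (percentile 99.96). Nr4a1 had 7, 4 and 3 models and Nr4a3 had 7, 3 and 1, while Fos had 2, 1 and 1. The endoplasmic reticulum stress list had 7 of 25 (percentile 98.2), with Ddit3 at 6, 3 and 3 models. Interferon-induced genes had 7 of 25 (percentile 96.4), with Oas2 at 4, 1 and 2 models. When a lead of at least 2 models was required, these last lists stood at percentiles 80.5 and 75.1. The endoplasmic reticulum stress list also stood at percentile 78.9 when models of the same span were counted once.

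The 20 genes with the largest lead in hypothalamus included Nefh and Srcin1. Nefh, the heavy neurofilament subunit (chromosome 11, 4938751 to 4949536), had 28 models in hypothalamus and 1 in each other tissue. Srcin1, a synaptic signalling adaptor (chromosome 11, 97509329 to 97575417), had 26 and 1 in each other tissue. Lrp8, a reelin receptor (chromosome 4, 107802158 to 107877537), had 25 in hypothalamus and 2 in each other tissue, and Nrcam, a neuronal adhesion molecule, had 20 against 2 and 2. Cacna1g, a T-type calcium channel, had 24 models in hypothalamus, 6 in adipose and 4 in liver. Sdccag3, with 33 models in hypothalamus, 4 in adipose and 5 in liver, had the largest lead among genes whose names passed the filter on symbols. Its symbol was not matched in GENCODE. Aifm3 had 26 models in hypothalamus and 3 in each other tissue, and Tnrc6a had 26 against 4 and 4.

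Of 29 genes of synaptic transmission, 14 had the most models in hypothalamus (percentile 97.3). Shank1, a postsynaptic scaffold, had 17 models there and 1 in each other tissue, and Gria2, a glutamate receptor subunit, had 14 against 3 and 3. Oligodendrocyte and myelin markers had 11 of 25 (percentile 98.97), with Mobp, a myelin-associated protein, at 9 models in hypothalamus, 3 in adipose and 4 in liver. Markers of thalamic, striatal and cortical neurons, fixed to look for tissue from outside the hypothalamus, had 11 of 26 (percentile 97.7), among them Cux2 with 11 models against 2 and 5. The hypothalamic neuropeptides had 8 of 32 at percentile 94.2, including Agrp, an appetite-stimulating peptide, with 4 models against 2 and 2, and Kiss1 with 3 against 1 and 1. With a lead of at least 2 models the synaptic list stood at percentile 80.4 and the oligodendrocyte list at 87.8, and counting models of the same span once put the oligodendrocyte list at 87.5.

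The 20 genes with the largest lead in liver included Alb and Apoa1. Alb, the gene of serum albumin (chromosome 5, 90400803 to 90572250), had 11 models in liver and 1 in each other tissue. Apoa1, the main protein of high-density lipoprotein (chromosome 9, 46225204 to 46232329), had 13 in liver, 2 in adipose and 1 in hypothalamus. Gcgr, the glucagon receptor, had 11, 2 and 1 in that order, and Gckr, the glucokinase regulator, had 11, 1 and 2. Serpina1a, an alpha-1 antitrypsin gene (chromosome 12, 103645156 to 103957014), had 32 models in liver and 2 in each other tissue, and Mug1, a protease inhibitor of plasma, had 26 in liver, 1 in adipose and 2 in hypothalamus. Aspdh, with 19 models in liver and 1 in each other tissue, and Tomm40l, with 19 in liver, 2 in adipose and 3 in hypothalamus, ranked directly after Mug1. Serpina1a and Mug1 lie among near-identical copies, so the assignment of their models to a single gene is uncertain.

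There were 5 lists at the 100th percentile in liver. Bile acid synthesis and transport had 13 of 23 members with the most models there, including Slco1a1, a bile acid and drug transporter, with 10 models against 1 and 1, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, with 2 against 1 and 1. Xenobiotic metabolism had 16 of 41, including Cyp3a25 with 9 against 2 and 2, and Cyp2e1 with 4 against 1 and 1. Liver genes that are sex-biased or regulated by growth hormone, a list drawn up for liver, had 14 of 30, including Igf1 with 11 against 6 and 6. Acute phase and complement genes had 11 of 28, including Serpina3n with 10 against 3 and 3, and Saa1 with 6 against 1 and 1. Gluconeogenesis and glycolysis had 8 of 21, including Pck1, the gluconeogenic carboxykinase, with 5 against 1 and 1. Many cytochrome P450, Saa and Serpina3 genes have close paralogs, and their individual numbers are uncertain.

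Lipoproteins and lipid transport had 6 of 34 members with the most models in liver (percentile 97.9), with Apoc2 at 11 models in liver, 4 in adipose and 1 in hypothalamus. The circadian clock list had 5 of 18 (percentile 97.9), with Tef at 9 models against 3 in adipose and 2 in hypothalamus, and Per2 at 5 against 1 and 1. Cholesterol synthesis had 6 of 25 (percentile 98.6), with Dhcr7 at 10 models in liver, 1 in adipose and 7 in hypothalamus. Fatty acid oxidation and ketone synthesis had 6 of 27 (percentile 98.0), with Cyp4a10 at 9 models against 1 and 1. With a lead of at least 2 models the cholesterol list stood at percentile 88.5 and the fatty acid oxidation list at 85.3.

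**Figure D1:**
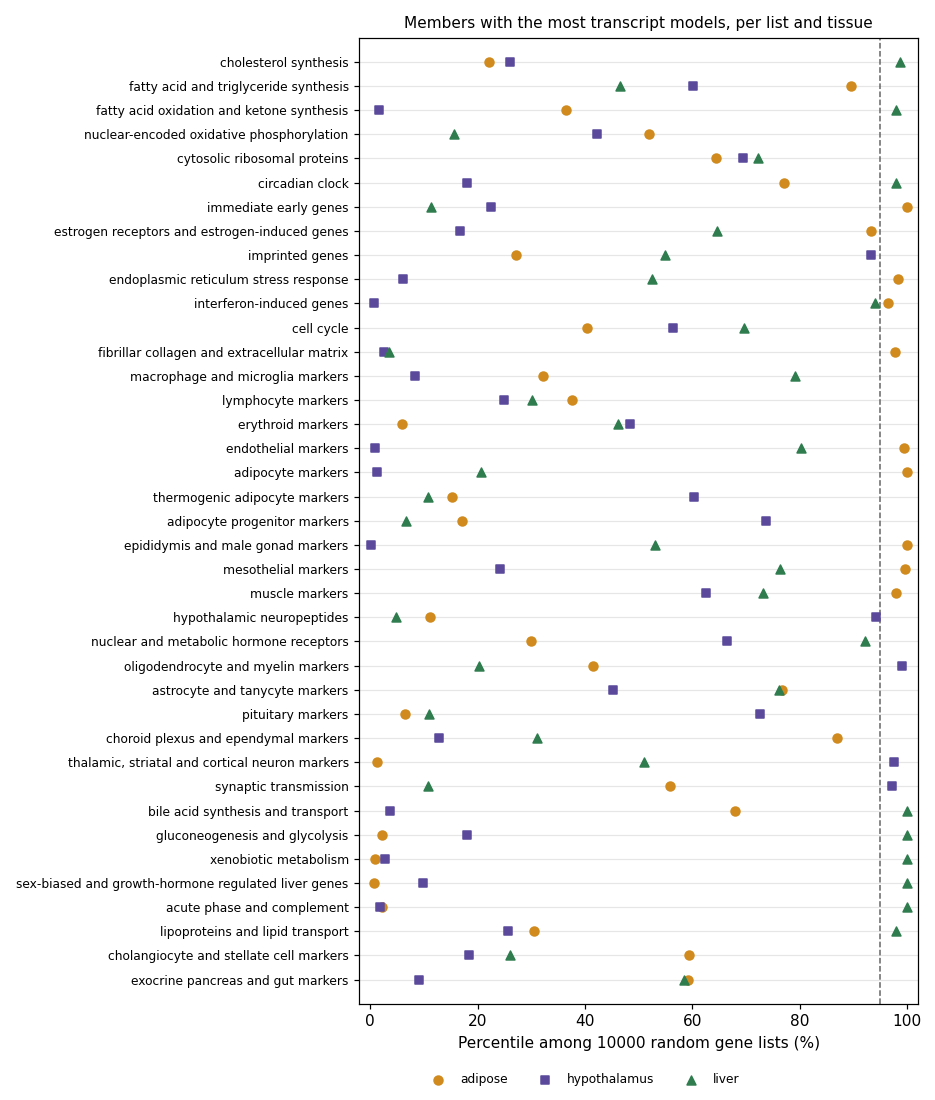
Percentile of each of 39 gene lists among 10000 matched random lists (horizontal axis, in percent), from the number of members with the most transcript models in adipose (circles), hypothalamus (squares) or liver (triangles). The dashed line marks percentile 95, which 9 lists reached in adipose, 3 in hypothalamus and 9 in liver.

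In all, 21 of the 117 percentiles were at or above 95, and 5% of 117 is 5.85. That number is a rough guide and no test. The percentiles are not independent, ties were divided on small counts, and many lists are markers of these same tissues. The remaining 18 lists reached 95 in no tissue. The estrogen receptors and estrogen-induced genes had 5 of 19 members with the most models in adipose (percentile 93.3), 3 in hypothalamus (16.7) and 2 in liver (64.6). Fatty acid and triglyceride synthesis had 6 of 22 in adipose (percentile 89.5), with Scd1, a fatty acid desaturase, at 8 models in adipose, 3 in hypothalamus and 1 in liver. The highest percentile was 92.2 for the nuclear and metabolic hormone receptors, in liver, 93.3 for the imprinted genes, in hypothalamus, and 86.9 for the choroid plexus and ependymal markers, in adipose. It was 79.2 for the macrophage and microglia markers, in liver, 76.7 for the astrocyte and tanycyte markers, in adipose, and 73.8 for the adipocyte progenitors, in hypothalamus. It was 72.5 for the pituitary markers and 60.3 for the thermogenic adipocyte markers, both in hypothalamus. It was 72.3 for the cytosolic ribosomal proteins and 69.6 for the cell cycle genes, both in liver. It was 51.9 for oxidative phosphorylation, 37.5 for the lymphocyte markers, 59.4 for the cholangiocyte and stellate cell markers and 59.1 for the exocrine pancreas and gut markers, all in adipose. It was 48.3 for the erythroid markers, in hypothalamus.

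Of the genes fixed in advance for their link to BPA or metabolism, some had the same model number in every tissue and others differed by a few models. Esr1, the estrogen receptor alpha (chromosome 10, 4611650 to 5005622), had 5 models in liver and 3 in each other tissue. Esr2, estrogen receptor beta, had 3 models in every tissue, and so did Srebf1, a regulator of lipid synthesis. Pparg, the main transcription factor of fat cell formation, had 5 models in adipose and in liver and 2 in hypothalamus. Fasn, the fatty acid synthase, had 1 in adipose, 3 in hypothalamus and 2 in liver. Lep, which encodes leptin, and Npy, an appetite peptide, had 1 model in every tissue. Of the remaining genes so fixed, Esrra had 1, 1 and 2 models in adipose, hypothalamus and liver, Ppara had 2, 3 and 3, Pomc had 5, 6 and 5, and Igf2 had 3, 3 and 4. Xist, which is transcribed from the inactive X chromosome, had 2 models in each assembly, and the Y-linked genes had 4, 2 and 3 for Ddx3y, 5, 8 and 2 for Eif2s3y and 5, 4 and 4 for Uty.

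Loci whose models carried no gene name were most numerous in adipose. There were 7052 in adipose, which was 22.8% of its loci (95% Wilson interval 22.4 to 23.3), 4683 in hypothalamus (16.5%, 16.0 to 16.9) and 2842 in liver (10.6%, 10.28 to 11.02). These intervals cover counting error only. In adipose 78.9% of them had no strand, against 71.0% in hypothalamus and 70.5% in liver. On the main chromosomes, 36.4% of the adipose loci overlapped a GENCODE exon (35.3 to 37.5), against 48.6% in hypothalamus (47.13 to 49.99) and 61.9% in liver (60.1 to 63.6). Among the loci with a strand these shares lay closer together, at 64.8% in adipose (62.3 to 67.2), 70.2% in hypothalamus (67.7 to 72.6) and 71.1% in liver (67.9 to 74.0). A further 18.5% in adipose lay within a gene without meeting an exon, against 8.37% in hypothalamus and 7.36% in liver. The share outside genes was 45.1% in adipose, 43.1% in hypothalamus and 30.8% in liver. Of the adipose loci 31.1% overlapped an unnamed locus of another tissue (29.99 to 32.15), compared with 42.1% in hypothalamus (40.7 to 43.5) and 62.0% in liver (60.2 to 63.8). The numbers of such loci were closer, at 2190, 1970 and 1762, and the shares depend on how many unnamed loci each tissue has.

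**Figure D2:**
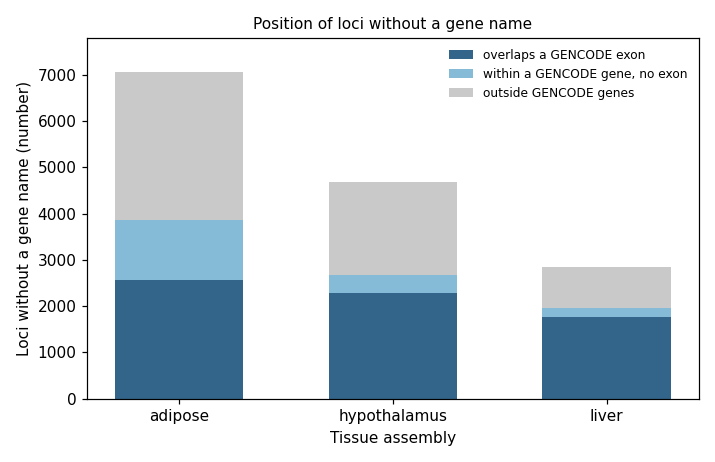
Number of loci without a gene name in each tissue assembly (vertical axis), divided by their position relative to GENCODE genes on the main chromosomes. Adipose had 1304 loci within genes that met no exon, against 392 in hypothalamus and 209 in liver.

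Among unnamed loci with a strand, those touching an exon of a GENCODE protein-coding gene on the same strand made up 16.8% in adipose (14.95 to 18.75), 16.2% in hypothalamus (14.3 to 18.3) and 11.8% in liver (9.82 to 14.2). Those touching an exon of a long intergenic noncoding RNA made up 10.8% in adipose (9.36 to 12.5), 14.3% in hypothalamus (12.5 to 16.2) and 13.4% in liver (11.3 to 15.9). Exons of processed pseudogenes were touched by 7.41% in adipose (6.18 to 8.85), 11.4% in hypothalamus (9.83 to 13.2) and 14.8% in liver (12.6 to 17.4).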

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

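All alternatives here were chosen after the data were seen. Between BPA and vehicle samples, no paired analysis was possible because the headings of the expression columns match neither the replicate numbers nor the groups of the labels. Tissues share column numbers, and pairing them by these was left out by choice, since columns without a sample or group were not used. None of the settings prepared beforehand for the BPA comparison (pseudocounts, filters, scalings, sample weights, a replicate block, leaving out samples) was run. Of 30 alternative values of the counts and shares reported, 18 stayed close to the reported value and 12 did not, where close means within 1.5 times for a count and inside the reported 95% Wilson interval for a share. Requiring a lead of at least 2 models lowered the genes with the most models to 1038 in adipose, 2609 in hypothalamus and 715 in liver, in the same order of tissues. Among unnamed loci, 1488 in adipose, 1360 in hypothalamus and 838 in liver had a strand, so the excess of adipose over hypothalamus was mostly in loci without one. A minimum span of 500 bp left 3505, 2784 and 1613 in the same order of tissues. With a reciprocal overlap of at least 50%, 19.5% of unnamed loci in adipose, 29.1% in hypothalamus and 45.2% in liver were shared with another tissue. Of the lists at or above percentile 95, 7 of 9 in adipose, 1 of 3 in hypothalamus and 7 of 9 in liver were there under all 3 alternatives run on lists. The list of thalamic, striatal and cortical neuron markers was the one in hypothalamus. Lists below 95 as reported that reached it in some but not all of these alternatives were the imprinted genes in hypothalamus (94.6 to 98.3 over the 3), the hypothalamic neuropeptides in hypothalamus (72.3 to 95.4), the nuclear and metabolic hormone receptors in liver (85.4 to 99.7), fatty acid and triglyceride synthesis in adipose (90.01 to 96.7) and interferon-induced genes in liver (85.3 to 96.8). The neuropeptides stood at 72.3 without matching on span and at 89.8 with a lead of 2. Depth is unknown for every assembly, and a difference in depth between tissues was not tested as a cause of any difference in model number.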

Other observations

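Imprinted genes, which are expressed from a single parental copy, had 12 of 29 members with the most models in hypothalamus, at percentile 93.3. The noncoding RNAs of the imprinted cluster on chromosome 12 were among them. Meg3 (109492439 to 109571774) had 16 models in hypothalamus, 9 in adipose and 4 in liver. Rian (109591537 to 109661711) had 13, 6 and 1 in that order, and Mirg (109730995 to 109749458) had 9, 2 and 1. Plagl1, an imprinted zinc finger gene on chromosome 10, had 38, 17 and 3, Zdbf2 had 14, 4 and 4, and Mest had 12, 3 and 4. These genes overlap other transcripts, and the random lists held protein-coding genes alone.

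Some unnamed loci with a strand had several models and overlapped no unnamed locus of another tissue. Whether they overlapped named models of the other tissues was not examined. The examples were picked by hand from the 5 per tissue with the most models, after their values and the genes they overlapped were seen, and are not always those with the most. In hypothalamus, a locus on chromosome 7 from 61009886 to 61311702 had 10 models and overlapped the long noncoding RNA A230006K03Rik, and another from 59451252 to 59565479 had 6 models and overlapped Snhg14, the host transcript of the small nucleolar RNAs of the Prader-Willi region. In liver, a locus on chromosome 10 from 111595880 to 111611652 had 16 models and overlapped the long noncoding RNA Gm30262. In adipose, where the most was 5 models, at loci that overlapped GENCODE genes, a locus on chromosome 12 from 79858962 to 79891133 had 4 models and met no GENCODE gene.

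The larger number of unnamed loci in adipose (7052, against 4683 and 2842) was examined for a technical origin, with both tests written before their values were seen and the comparison of tissues within the first chosen afterwards. If the extra loci were reads of genomic DNA spread evenly, loci without a strand and off exons should lie inside genes as often as evenly placed ones, but in adipose 30.9% did against 40.8%, a difference of -9.85 percentage points, and by the bound set beforehand that alone would exclude the explanation. That bound was set aside after the value was seen, because hypothalamus (-23.4) and liver (-20.5) lay further below even placement, so the test lacks a baseline and genomic DNA as a source of the adipose excess cannot be told apart from others. The test for unspliced RNA covered intronic unnamed loci without a strand that overlapped no unnamed locus of another tissue, 1095 in adipose. The prediction written beforehand did not name the restriction to loci without a strand. Genes holding such a locus in adipose numbered 172, and 23.8% of them had the most models in adipose, against 13.0% of other genes. Within groups of similar span the odds ratio was 1.65 (95% interval 1.16 to 2.35), which met the bound set beforehand. The ratio was 1.55 (0.978 to 2.44) in hypothalamus and 3.98 (1.88 to 8.43) in liver for their own loci. This test therefore lacks a baseline too, and cannot tell unspliced RNA apart from other sources of the adipose excess. Depth, library quality and a biological difference between the tissues were not tested and stay open.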
